A study of Homo sapiens with 6 samples.

How the data were processed

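Messenger RNA was sequenced in 6 libraries from 2 prostate cancer cell lines, C4-2B MDVR and H660. Each line gave 1 library with a control siRNA, 1 with PLXND1 siRNA 1 and 1 with PLXND1 siRNA 2, so each line has 1 control and 2 knockdown libraries. The reads were paired ends of 150 bases, per the labels' protocols. Per the submitters' processing notes, reads were aligned with HISAT, expression was computed with Cufflinks and the build was hg18; no versions are given there. The deposited values are FPKM, fragment numbers divided by exon length and by library size, computed by the authors for 58735 Ensembl gene IDs. All 58735 IDs are in GENCODE release 29, an annotation of GRCh38, and gene names, gene types, exon lengths and the coordinates given here come from that annotation. No filter was seen in the deposited table: genes at 0 are kept, and 34007 genes are above 0 in at least 1 library.

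The FPKM values multiplied by the summed exon length of the gene were whole multiples of 1 step per library, within a tolerance of 0.05 fragments, in 100.0% of the genes checked, which were those of at most 100 fragments (11224 to 13428 genes per library). For the genes above that, the check was not made. On that basis the number of fragments per gene was recovered from that step. The recovered totals run from 17655802 to 24105369 fragments per library. The total implied by the step was 0.92 to 1.08 times the recovered total, so each library carries a further factor whose source the notes do not give. The deposited FPKM values were used without removing it. In C4-2B MDVR it went with the treatment. The implied total was above the recovered one in the control (20733178 against 20502382). It was below in both knockdown libraries (20139104 against 21748669, and 16242467 against 17655802), and above in every H660 library. By limma's voom on the recovered fragments the median change of all genes in C4-2B MDVR was −0.09, against 0.02 as deposited. Intervals are 95% intervals from the fragment numbers (exact Poisson for a level, exact binomial for a ratio of 2 libraries); they cover counting error only.

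Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, for the 15638 genes with a mean FPKM of at least 1 over the 3 libraries of at least 1 line. The moderated test used an intensity trend and was two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The knockdown effect in both lines and the difference between the lines came from an additive fit of line and treatment, with 3 residual degrees of freedom; a line difference also had to reach 2-fold. The effect in each line and the difference of the effect between lines came from a fit of 4 groups, with 2 residual degrees of freedom. In that fit the spread comes from the 2 knockdown pairs alone, so the lone controls are assumed to vary like them. The labels do not say that the libraries came from separate cultures, and the 2 knockdown libraries of a line carry different siRNAs. The siRNA numbers do not pair the samples across lines in any other way. Beside the test, a rule of size counted genes with at least a 2-fold change the same way with both siRNAs, against 200 simulated draws with no effect and a shared control. The noise of these draws came from the difference between siRNA 1 and siRNA 2 in the same line. It therefore also holds differences in effect between the siRNAs, and the lone control was given the same noise.

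Gene lists were written before the data were examined, as were the tests and the rule for named genes. Of 31 lists, 29 had at least 5 measured members. They were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Members of a list were also adjusted over the list alone. A list's median change in 1 library is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins.

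The rule for named genes took PLXND1 first, in each library. For both lines together it took the 10 largest changes each way among genes that passed with the same sign in all 4 knockdown libraries; since fewer passed, the places were filled with genes that did not pass, with a mean FPKM of at least 1 in both lines and the same sign in all 4, by the size of the smallest of their 4 changes. For each line it took 10 genes each way with the same sign for both siRNAs, by the smaller of their 2 changes. For the difference of the effect between lines and for the line difference it took the 5 largest each way past the threshold; for each list, up to 4 members with the largest change; and in each line's control the 4 highest members of the androgen receptor and neuroendocrine lists. A few genes that the rule takes are not given. Genes with no name and genes with symbols that start with MIR, SNOR, SCARNA, RNU, RN7S, RNY or VTRNA were not named, so that short RNAs with other symbols could be, and where several IDs share a symbol the highest was used. After the data were seen, a second ranking was added for each line with the same order among protein-coding nuclear genes of at least 50 fragments on average, 12 each way.

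The limma fit, its calls, camera and the rule of size were tested on simulated data in which 200 genes were changed by known folds. The recovery of fragments, the draws with no effect, the random lists and the explanation tests were not tested in that way. In the simulated data every gene of a line had the same dispersion, taken from the knockdown pair of the line. In the measured libraries the spread varied between genes, so the shares recovered may be too high for this design. For the effect in both lines, 54.0% of 2-fold and 98.0% of 8-fold changes were recovered, with 6 false calls among 15473 unchanged genes. In C4-2B MDVR alone 6.0% of 2-fold, 60.0% of 4-fold and 90.0% of 8-fold changes were recovered, and in H660 alone 0% of 2-fold, 56.0% of 4-fold and 88.0% of 8-fold changes. Of 16-fold changes 98.0% were recovered in C4-2B MDVR. In the measured libraries OASL, at 3.93 and 4.13 log2 units with the siRNAs in that line, did not pass. For the difference of the knockdown effect between lines 0% of 2-fold, 10.0% of 4-fold and 54.0% of 8-fold changes were recovered. The line difference itself was not simulated.

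Alternatives covered the pseudocount (0.1 and 5), the filter on low values, scaling by median ratios, quantile normalization, leaving out short RNAs or mitochondrial genes, the variance model, an adjusted p of 0.10, each library left out in turn and the siRNA number as a replicate block. Leaving out short RNAs or mitochondrial genes always included a rescaling of the libraries, also where only the leaving out is named. The fit by limma's voom on the recovered fragment numbers and the fit without mitochondrial genes were chosen after the data were seen. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Nothing was left out: all 6 columns of the table were used.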

Results

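The data were 6 messenger RNA libraries from 2 human prostate cancer cell lines. C4-2B MDVR is a derivative of the C4-2B line that grows in the presence of enzalutamide, an inhibitor of the androgen receptor. H660 is the NCI-H660 line, a model of neuroendocrine prostate cancer. Each line had 1 library with a control siRNA and 1 library with each of 2 siRNAs against PLXND1, which encodes Plexin D1, a cell-surface receptor for semaphorins. The series asks what this receptor does for the shift of prostate cancer cells that resist treatment towards a neural state. In C4-2B MDVR the control library held 20502382 fragments assigned to genes, the siRNA 1 library 21748669 and the siRNA 2 library 17655802. In H660 these totals were 22884829, 21911440 and 24105369. There was no repeat of any control or of any siRNA within a line, and the labels do not say that the libraries came from separate cultures. Mitochondrial genes gave 3.38% of the fragments in the C4-2B MDVR control, 7.44% and 6.83% with siRNA 1 and siRNA 2, and 8.58%, 9.47% and 9.64% in the H660 control and knockdown libraries, so the C4-2B MDVR control stood apart from the other 5.

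PLXND1 was lower in all 4 knockdown libraries than in the control of its line, and the decrease was much larger in C4-2B MDVR. The gene (ENSG00000004399) lies on chromosome 3 from 129555175 to 129606818 in GRCh38, on the minus strand. In C4-2B MDVR its level was 7.40 FPKM in the control (95% interval 7.03 to 7.79, from 1495 fragments) and 2.33 ± 1.08 FPKM in the knockdown libraries (SD, n = 2), which is 31.5% of the control. With siRNA 1 it was 1.57 FPKM, 21.2% of the control (18.7% to 24.0%), and with siRNA 2 it was 3.10 FPKM, 41.8% of the control (37.7% to 46.4%). In H660 it was 9.13 FPKM in the control, from 2201 fragments, and 7.58 ± 0.0563 FPKM in the knockdown libraries (SD, n = 2), or 83.0% of the control. The single H660 libraries were at 83.5% (78.3% to 88.9%) and 82.6% (77.6% to 87.9%) of the control. The intervals cover counting error only. On the log2 scale PLXND1 did not pass the limma threshold in either line, at −1.37 ± 0.31 (SE) in C4-2B MDVR (adjusted p = 0.711) and −0.24 ± 0.31 in H660.

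**Figure D1:**
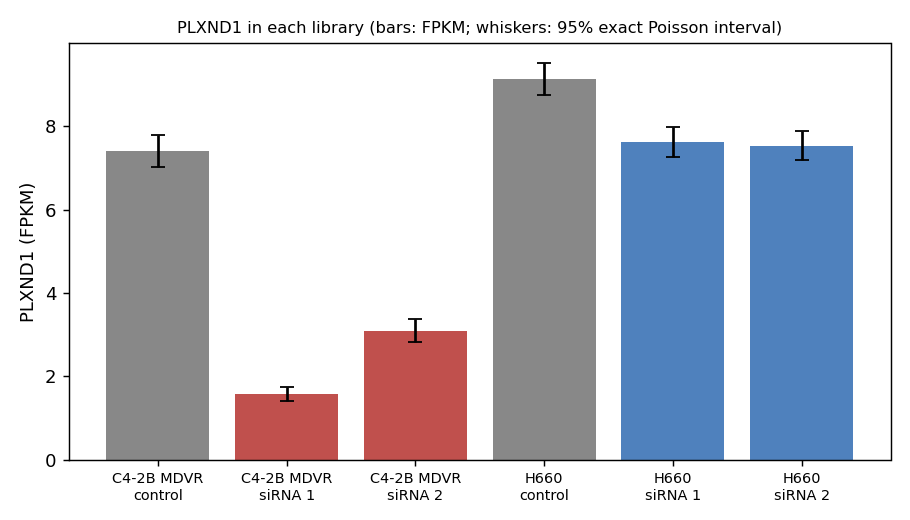
PLXND1 level in FPKM (vertical axis) in each of the 6 libraries, as bars with whiskers for the 95% counting interval. The C4-2B MDVR knockdown libraries sit at 1.57 and 3.10 FPKM against 7.40 in their control, and the H660 knockdown libraries at 7.62 and 7.54 against 9.13.

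In C4-2B MDVR, genes with high ratios of both knockdown libraries over the control included antiviral genes that cells switch on after interferon or foreign RNA. OASL, which enhances RIG-I signalling, was at 0.329 FPKM in the control and 19.3 and 22.2 FPKM with siRNA 1 and siRNA 2, a log2 difference of 4.03 ± 0.17 (SE). IFIT1, which binds viral RNA, was at 0.596, 19.5 and 22.1 FPKM, and its relatives IFIT3 and IFIT2 were higher by 3.69 and 3.23 log2 units. The chemokine gene CCL5 (3.35), the membrane proteins BST2 (2.56) and IFITM1 (2.50), which restrict viruses, and the interferon-induced IFI6 (2.71) and ISG15 (2.23) were also higher with both siRNAs. CDKN1A, which encodes the cell-cycle inhibitor p21 and is a target of p53, was at 47.5 FPKM in the control and 422 and 346 FPKM in the knockdown libraries (2.98 ± 0.19). PHLDA3, a p53 target that restrains AKT, was 2.02 log2 units higher, and the mitochondrial transfer RNA MT-TT 2.66 units higher. RAET1L, a ligand of the NKG2D receptor of natural killer cells, was listed at 0 in the control and at 4.69 and 4.30 FPKM in the knockdown libraries.

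Other genes had low ratios of both C4-2B MDVR knockdown libraries over the control. Adjusted over all genes, 0 of them passed. ACADL, a dehydrogenase of fatty acid oxidation, was −1.62 ± 0.19 log2 units from the control, at 1.53 and 2.01 FPKM with the siRNAs, and PEX10, needed for peroxisome assembly, was at 23.9, 9.53 and 9.31 FPKM (−1.26 ± 0.16). The fatty acid desaturase genes FADS1 (−1.16 ± 0.16) and SCD (−1.01 ± 0.16) and the sterol regulator INSIG1 (−1.11 ± 0.19) were lower too. MCCC2, of leucine breakdown, was at −1.14, the splicing factor gene SRSF1 at −1.06, the kinase gene ICK at −1.02, SYCP3, of meiotic chromosomes, at −0.88 and LNP1 at −0.84. The cancer-testis gene SSX2B was at −1.71, although its reads are hard to tell from those of its close copies. The pseudogenes AP000553.6 (−2.63), AC004975.1 (−1.57), AL139396.1 (−1.50) and IGLVIVOR22-1 (−1.29) and the noncoding genes RF00153 (−2.21), AC106820.3 (−1.21) and LINC01419 (−1.18) completed those named. Of these, AP000553.6 and RF00153 each had 9, 0 and 1 fragments in the control and with siRNA 1 and siRNA 2.

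No single gene passed the limma test in C4-2B MDVR after adjustment over all genes: 0 of 15638, with 921 at an unadjusted p under 0.05 (585 higher and 336 lower, where chance gives 782) and 0 by voom, which had 991 at that level. The lowest adjusted p was 0.0901, for OASL and IFIT1. By size alone, 102 genes were at least 2-fold higher and 44 at least 2-fold lower with both siRNAs out of 12888, and 7 differed in opposite directions. Simulated libraries with no effect and a shared control gave 165 such genes on average, against 146 observed. Among protein-coding nuclear genes of at least 50 fragments the values were 80.1 simulated and 46 observed. The simulated noise came from the difference of the 2 siRNAs, which was far beyond counting error (chi-square per degree of freedom 87.4, against 10.7 in H660). If the siRNAs differ in effect, the simulated counts are too high. They do not decide whether the shared changes exceed noise.

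As groups, the interferon, p53 and mitochondrial lists rose in C4-2B MDVR by camera, in libraries whose control also had the low mitochondrial share. Of 35 measured interferon response genes, all 35 were above the control, 18 rose when adjusted over the list alone and 0 when adjusted over all genes, with a median of 0.84 log2 units (adjusted p = 1.98e-27, and adjusted p = 0.213 with an estimated correlation). Members that rose over the list alone included the antiviral HERC5 (1.78), OAS1 (1.74) and the RNA sensor DDX58 (1.54), besides OASL and IFIT1. The p53 list had a median of 0.79 over 27 genes, of which 15 rose adjusted over the list alone and 0 over all genes (adjusted p = 1.45e-19, and adjusted p = 0.294 with an estimated correlation). TP53INP1 (1.63), BTG2 (1.59), TP53I3 (1.47) and SESN1 (1.46), which act in growth arrest and the response to oxidants, were among them. All 13 mitochondrially encoded transcripts rose adjusted over the list alone, and 0 over all genes, with a median of 1.31 (adjusted p = 1.45e-19, and adjusted p = 0.412 with an estimated correlation). MT-ND1, a subunit of respiratory complex I, was at 1372 FPKM in the control and at 4760 and 4169 FPKM in the knockdown libraries. Quantile normalization put that median at 0.01, since these transcripts hold the top ranks in every library.

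**Figure D2:**
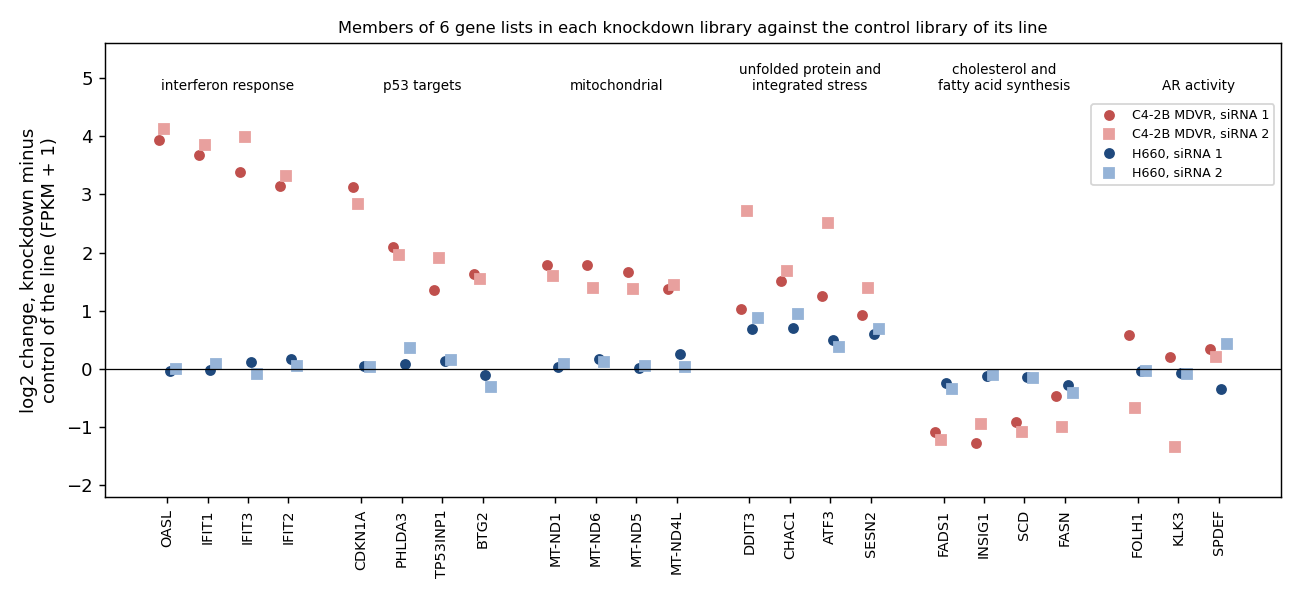
Log2 change against the control of the same line (vertical axis) of named members of 6 gene lists, 1 point per knockdown library. The antiviral gene OASL lies at 3.93 and 4.13 in C4-2B MDVR and at −0.03 and −0.00 in H660, while the stress gene CHAC1 lies above 0 in all 4 libraries, at 1.51, 1.69, 0.70 and 0.94.

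The unfolded protein and integrated stress response list rose in C4-2B MDVR by camera, with a median of 0.37 over 35 genes (adjusted p = 4.42e-06, and adjusted p = 0.778 with an estimated correlation). CHAC1, which degrades glutathione, was its 1 member that rose adjusted over the list alone (1.60), and 0 did over all genes; ATF3 (1.88) and DDIT3 (1.87), transcription factors of that response, did not pass. The list's median was 0.07 with siRNA 1, which became −0.22 with short RNAs left out and −0.01 with quantile normalization, and 0.66 with siRNA 2; without C4-2B MDVR knockdown replicate 2 the call was lost (adjusted p = 0.374). The cholesterol and fatty acid list fell, with a median of −0.15 over 33 genes (adjusted p = 2.07e-05, and adjusted p = 0.703 with an estimated correlation; 0.0829 without C4-2B MDVR knockdown replicate 2). FADS1, INSIG1 and SCD were the 3 members that fell adjusted over the list alone, with 0 over all genes. Of the apoptosis list, with a median of 0.12 over 29 genes, PMAIP1, which encodes the cell-death protein NOXA, was the 1 that rose adjusted over the list alone (1.21), and of the NF-kB list, with a median of 0.21 over 19 genes, the 1 was CCL5; 0 of either list passed over all genes. Camera called both lists higher (adjusted p = 0.0216 and 0.00471), with adjusted p = 0.62 and 0.778 with an estimated correlation. The apoptosis call was lost without C4-2B MDVR knockdown replicate 1 (0.165) or 2 (0.0946) and without H660 knockdown replicate 1 (0.0556) or 2 (0.0555), and the NF-kB call without C4-2B MDVR knockdown replicate 2 (0.153).

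A further 7 lists were called in C4-2B MDVR, and no member of them passed either adjustment. Camera called the G2 and M phase list lower (median −0.21, adjusted p = 5e-06, and adjusted p = 0.798 with an estimated correlation), with CCNB1 (−0.68) and CDC20 (−0.63), which drive mitosis, among its members. The MYC target list was called lower too (−0.13, adjusted p = 0.0044, and adjusted p = 0.8 with an estimated correlation), with the polyamine enzyme gene ODC1 at −0.61. These 2 medians were −0.48 and −0.44 with siRNA 1 but 0.02 and 0.18 with siRNA 2, and without C4-2B MDVR knockdown replicate 1 the adjusted p was 0.982 and 0.32 with the direction reversed. The hypoxia (0.21), YAP (0.21), luminal (0.17), oxidative phosphorylation (0.14) and ribosomal protein (0.16) lists were called higher. With an estimated correlation the adjusted p was 0.62 for hypoxia and YAP, 0.778 for luminal and oxidative phosphorylation and 0.839 for ribosomal proteins. Leaving out short RNAs and rescaling each library to the same summed FPKM moved the median of all genes from 0.02 to −0.18. By that median, the rescaling lowered the knockdown libraries against the control. As deposited, the sum over all genes, short RNAs included, was 273965 in the control and 336099 and 338241 with the siRNAs. The sums without short RNAs, which the rescaling equalised, are not given. Leaving out the short RNAs and rescaling were not tested apart from each other. There the medians of the hypoxia (−0.05), luminal (−0.09), oxidative phosphorylation (−0.15), ribosomal protein (−0.14) and apoptosis (−0.12) lists were negative but above that of all genes. YAP was at 0.03, NF-kB at 0.08, the stress list at 0.09, p53 at 0.50, interferon at 0.65 and mitochondrial transcripts at 1.01. The lists called lower went further down there, to −0.48 for G2 and M phase, −0.42 for MYC targets and −0.43 for cholesterol. Quantile normalization also turned the ribosomal proteins (−0.03). Of the 14 calls it lost 2, a pseudocount of 0.1 lost 1, and leaving out mitochondrial genes lost 1 of 13. With the siRNA number as a replicate block the oxidative phosphorylation call was lost (adjusted p = 0.0643). Without C4-2B MDVR knockdown replicate 1 the adjusted p was 0.179 for hypoxia, 0.42 for oxidative phosphorylation and 0.861, reversed, for luminal genes, and without replicate 2 it was 0.153 for YAP and 0.0881, reversed, for ribosomal proteins; without H660 knockdown replicate 1 or 2 it was 0.181 and 0.176 for YAP and 0.0556 and 0.0555 for ribosomal proteins. Of 14 lists called by camera, 6 lost the call without C4-2B MDVR knockdown replicate 2 and 6 without replicate 1, and 0 were called with an estimated correlation or by fry. In simulated data a true shift of the interferon list by 1 log2 unit in C4-2B MDVR was also missed with an estimated correlation (adjusted p = 0.216). There camera at the preset correlation called 1 list besides the shifted one. The simulated genes were drawn independently, so this does not show which setting is right for genes that move together.

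The lineage lists that the series centres on gave no call in C4-2B MDVR. The androgen receptor list had 15 of 38 members above the control and 23 below, with 0 passing adjusted over the list alone or over all genes (camera adjusted p = 0.116). Among its members with the highest control levels were FOLH1, which encodes prostate-specific membrane antigen (203, 304 and 127 FPKM in the control and with siRNA 1 and siRNA 2), KLK3, which encodes prostate-specific antigen (197, 228 and 77.5 FPKM), and SPDEF (196, 250 and 225 FPKM). Over the 35 members expressed in the line the median was 0.23 with siRNA 1, the 99.4th percentile of random lists, and −0.24 with siRNA 2, the lowest of all. Leaving out short RNAs and rescaling the libraries turned the median of all 38 members with siRNA 1 from 0.22 to −0.01. That with siRNA 2 moved from −0.22 to −0.50, and that of the line mean from −0.02 to −0.31. SLC45A3 (−1.20), ACPP (−1.11) and KLK2 (−0.86) had the lowest mean values. The neuroendocrine list had a median of 0 over its 44 members, and 0 passed either adjustment (camera adjusted p = 0.63). By sign alone 20 members were above the control and 24 below, but unchanged genes are among these. Over the 12 members expressed in the line the median was −0.17 with siRNA 1 and 0.07 with siRNA 2. For the mean of both siRNAs it was −0.14, the 2.85th percentile of random lists. HES6, a transcription factor gene of neuronal differentiation, was at 39.4, 15.4 and 39.3 FPKM and SYT4, of vesicle release, at 26.1, 69.3 and 28.4 FPKM. Of the 26 plexins, semaphorins and their partners measured, 0 passed (camera adjusted p = 0.594), with SEMA3F at 0.82 and NRP1 at 0.70.

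In H660 the stress response list was the 1 list called. It had a median of 0.39 log2 units, with 34 of 35 genes above the control, and its median was 0.29 with siRNA 1 and 0.46 with siRNA 2 over expressed members (camera adjusted p = 1.11e-05, and adjusted p = 0.985 with an estimated correlation). Members with high values were the cystine transporter gene SLC7A11 (0.82), CHAC1 (0.82), DDIT3 (0.79) and the serine synthesis gene PSAT1 (0.76); 0 of 35 rose adjusted over the list alone or over all genes. The call was lost without H660 knockdown replicate 2 (adjusted p = 0.151), and without C4-2B MDVR knockdown replicate 1 or replicate 2 the number of lists called was 2. The interferon list (median 0.02, −0.02 with short RNAs left out, adjusted p = 0.743), the mitochondrial list (0.14, adjusted p = 0.299) and the p53 list (median −0.03 but mean 0.08, adjusted p = 0.72) were not called. The neuroendocrine list (−0.05) and the androgen receptor list (−0.02) each had an adjusted p of 0.72, and the plexin and semaphorin list had a median of −0.16 (adjusted p = 0.113). Of the neuroendocrine genes with high H660 control levels, NKX2-1 was at −0.21, UCHL1 at 0.11 and STMN1 at −0.07. Androgen receptor list members with the highest H660 control levels were NDRG1 (−0.25), NCAPD3 (−0.19), CAMKK2 (−0.04) and ZBTB10 (0.55).

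Single genes higher with both siRNAs in H660 included TPD52, an oncogene of vesicle traffic, at 15.5 FPKM in the control and 52.8 and 48.8 FPKM in the knockdown libraries (1.65 ± 0.17, adjusted p = 0.574). TMED7, a cargo receptor of the secretory pathway, was at 2.70, 10.6 and 9.33 FPKM (1.57 ± 0.18), and MZT1, of the spindle pole, was at 1.53. MOB4 (1.32), the ubiquitin-conjugating enzyme genes UBE2D1 (1.30) and UBE2W (1.24), LYPLA1 (1.20), the phosphatase gene PPP1CB (1.20), NECAB1 (1.18) and IER3IP1 (1.09) followed. SMN1 (1.77), NPIPA7 (1.20) and RPL29P11 (2.46) were higher as well, but they have near copies elsewhere in the genome that share reads. MT-TR, a mitochondrial transfer RNA, was listed at 0 in the control and at 33.4 and 32.8 FPKM. Lower genes were the calcium channel subunit gene CACNG5 (−0.82), the cytokine gene IL17C (−0.82), GPR142 (−0.61), BEND3 (−0.61), ZNF594 (−0.60), COPS9 (−0.59), the surfactant gene SFTPB (−0.57), TCERG1L (−0.56) and CCDC188 (−0.55), besides MAGED4B (−1.76), which has a near copy, AC126755.2 (−1.16), PHOSPHO1 (−0.61), the pseudogene AC139272.1 (−2.22) and the noncoding AC087276.1 (−1.93). The other genes that the rule took were noncoding RNAs and pseudogenes, from RNA5SP18 (2.09), AC124016.2 (1.47), AC100814.1 (1.45) and AC013410.2 (1.40) on the higher side to RNA5SP82 (−1.96), RF00409 (−1.82), AL033528.1 (−1.77), RNA5SP187 (−1.75), SPCS2P4 (−1.43), RF00108 (−1.31) and AC002428.2 (−1.21) on the lower.

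No gene passed the limma test in H660: 0 of 15638, with 647 at an unadjusted p under 0.05 (447 higher and 200 lower, where chance gives 782) and 0 by voom, with 498. The lowest adjusted p was 0.0772, for MT-TR. By size, 59 genes were at least 2-fold higher and 39 lower with both siRNAs among 13946, 98 in all, where simulations with no effect gave 115 on average and 145 at most. Among protein-coding nuclear genes of at least 50 fragments 13 were higher and 2 lower, 15 in all, where the simulations gave 1.67 on average and 6 at most. That subset was chosen after the data were seen. The simulations let the lone control vary like the knockdown pair, so an unusual H660 control cannot be told apart from a shared effect of the siRNAs.

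Taking both lines together, 0 of 15638 genes passed adjusted over all genes, and the 10 genes taken on the higher side, with the same sign in all 4 knockdown libraries, included CHAC1, DDIT3 and SESN2 of the stress response list. PMAIP1 was at 2.14 FPKM in the C4-2B MDVR control and 6.22 and 6.31 FPKM with the siRNAs, and at 32.5, 61.9 and 59.7 FPKM in H660, a difference of 1.05 ± 0.12 log2 units (adjusted p = 0.898; 0.00347 adjusted over the apoptosis list alone). CHAC1 was 1.21 ± 0.20 higher, from 9.87 to 29.9 and 34.0 FPKM and from 2.63 to 4.88 and 5.96 FPKM, and DDIT3, the stress factor CHOP, 1.33 ± 0.49 higher. SESN2 (0.90 ± 0.18), which restrains mTORC1, the stress cytokine gene GDF15 (0.97 ± 0.25) and RND3 (1.13 ± 0.31) were also higher in all 4 libraries. Noncoding or pseudogene entries with the same sign were MT-TD (1.51), RPL29P11 (1.54), AC003965.2 (1.25) and AC135721.1 (1.13). On the lower side the protein-coding gene was BEND3 (−0.58 ± 0.13), with AC139272.1 (−1.57), SPCS2P4 (−1.04), AC004057.1 (−0.96), RF00569 (−0.81), AC084018.1 (−0.79), RNA5SP383 (−0.70), AP000759.1 (−0.62), ZNRF2P1 (−0.60) and AC073210.1 (−0.57).

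The stress response list rose in both lines together, with all 35 genes above 0 and a median of 0.36 (camera adjusted p = 8.4e-12, and adjusted p = 0.527 with an estimated correlation). Of these, CHAC1 and SESN2 rose adjusted over the list alone, 2 of 35, and 0 over all genes. Interferon (0.50), p53 (0.47) and mitochondrial (0.75) lists rose by camera too, each with adjusted p = 0.527 with an estimated correlation and 0 members passing either adjustment. The cholesterol list fell (−0.12, adjusted p = 9.71e-05, and adjusted p = 0.527 with an estimated correlation). Each line adds to this effect through its 1 control, so without the C4-2B MDVR control the fit held the H660 effect alone, where the stress list was called (adjusted p = 1.08e-05) and interferon (0.738), p53 (0.724), mitochondrial transcripts (0.266) and cholesterol (0.499) were not. Of 14 lists called, 7 lost the call without C4-2B MDVR knockdown replicate 1, and 0 were called with an estimated correlation or by fry. The other 9 had medians between −0.10 and 0.14, with adjusted p from 0.527 to 0.774 with an estimated correlation. Of these, calls were also lost without C4-2B MDVR knockdown replicate 2 (YAP 0.142, NF-kB 0.225, ribosomal proteins 0.605 and reversed), H660 knockdown replicate 1 (YAP 0.0726) and H660 knockdown replicate 2 (RNA interference machinery 0.158, ribosomal proteins 0.14). Without the H660 control the fit held the C4-2B MDVR effect alone, where RNA interference machinery was not called (0.359). Leaving out short RNAs and rescaling the libraries moved the median of all genes to −0.12 and turned the apoptosis (−0.03), hypoxia (−0.05), luminal (−0.06) and ribosomal protein (−0.08) lists negative. It put the stress list at 0.18, interferon at 0.36, p53 at 0.30 and mitochondrial transcripts at 0.57. Cholesterol was then at −0.30, G2 and M phase at −0.27, MYC targets at −0.26 and RNA interference machinery at −0.23. Quantile normalization turned the ribosomal proteins (−0.02) and put the mitochondrial transcripts at 0.03. Of the 14 calls it lost 4, and a pseudocount of 0.1 lost 1. By limma 654 genes had an unadjusted p under 0.05 (400 higher and 254 lower, where chance gives 782), against 754 by voom, which also called 0. The androgen receptor list (−0.05, adjusted p = 0.113) and the neuroendocrine list (−0.04, adjusted p = 0.296) were not called.

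**Figure D3:**
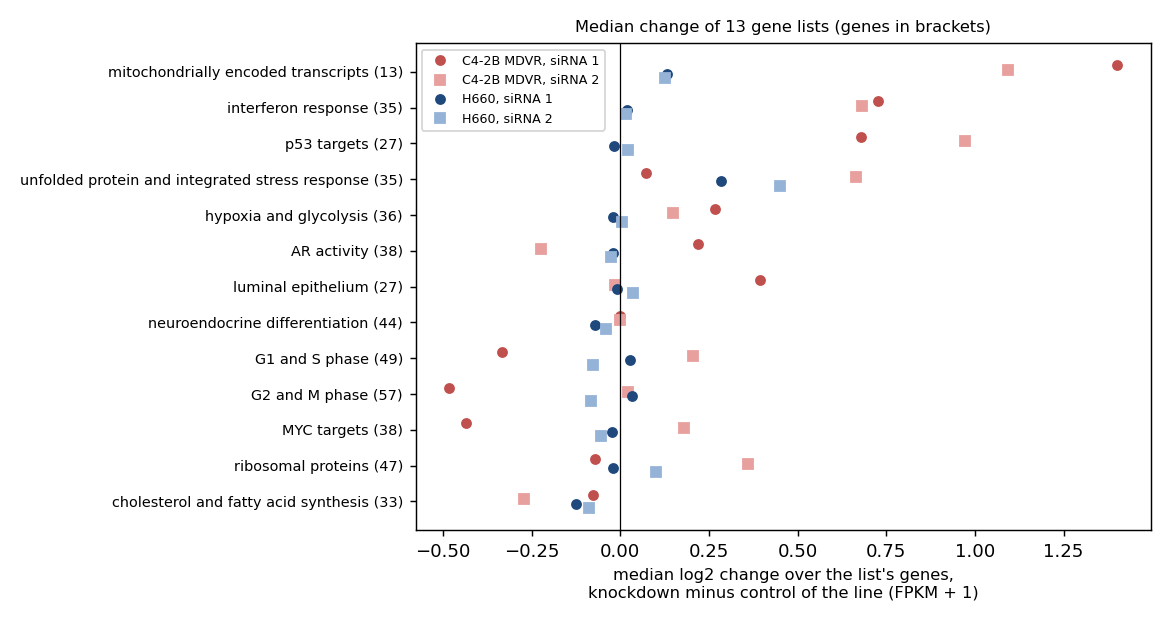
Median log2 change (horizontal axis) of 13 gene lists, 1 point per knockdown library against the control of its line, over all measured members. The stress response list lies at 0.07 and 0.66 in C4-2B MDVR, with the first at −0.22 when short RNAs are left out, and at 0.28 and 0.45 in H660; the interferon list lies at 0.73 and 0.68 in C4-2B MDVR and at 0.02 and 0.02 in H660, with the H660 values at −0.01 and −0.02 when short RNAs are left out.

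The knockdown effect differed between the lines for 6 lists by camera and for 0 single genes by limma (701 at an unadjusted p under 0.05, 330 higher and 371 lower; 0 by voom, with 754). The interferon effect was lower in H660 than in C4-2B MDVR by a median of −0.74 log2 units, with 13 of 35 genes lower adjusted over the list alone and 0 over all genes (adjusted p = 1.27e-20, and adjusted p = 0.283 with an estimated correlation). The p53 effect differed by −0.83, with 9 of 27 genes lower adjusted over the list alone (adjusted p = 3.27e-13, and adjusted p = 0.435 with an estimated correlation), and the mitochondrial effect by −1.17, with 10 of 13 (adjusted p = 1.87e-13, and adjusted p = 0.586 with an estimated correlation); 0 of these passed over all genes. Quantile normalization put the mitochondrial difference at −0.14. The G2 and M phase (0.23, adjusted p = 9.27e-05), cholesterol (0.10, adjusted p = 0.0316) and hypoxia (−0.20, adjusted p = 0.0447, 0.04 with short RNAs left out, where the median of all genes moved from −0.03 to 0.14) lists also differed, each with adjusted p = 0.83 with an estimated correlation and 0 members passing. Leaving out short RNAs put G2 and M phase at 0.46 and cholesterol at 0.32, and interferon at −0.58, p53 at −0.59 and mitochondrial transcripts at −0.93. The stress response effect was not called different (−0.11, adjusted p = 0.519; 0.15 with short RNAs left out and 0.05 with quantile normalization), nor was that of the androgen receptor (0.03, or 0.27 with short RNAs left out) or neuroendocrine (−0.04) lists. With a knockdown library left out, the spread came from the 1 pair of the other line, and there the interferon, p53 and mitochondrial lists were still called. Without C4-2B MDVR knockdown replicate 1 the adjusted p was 0.701 for G2 and M phase and 0.524 for hypoxia, and without replicate 2 it was 0.477 for cholesterol and 11 lists were called; without H660 knockdown replicate 1 it was 0.0569, 0.328 and 0.256 for these lists, with 3 lists called, and without replicate 2 it was 0.258 for hypoxia and 0.162 for cholesterol. With the siRNA number as a replicate block the hypoxia call was lost (adjusted p = 0.0552). Quantile normalization and a pseudocount of 0.1 each lost 2 of the 6 calls, and leaving out mitochondrial genes lost 1 of 5. These differences rest on 1 control per line. The difference in the PLXND1 effect itself was 1.13 ± 0.44 log2 units and did not pass (adjusted p = 0.985).

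The siRNAs resembled each other to different degrees in the lines. Across 12888 genes in C4-2B MDVR the log2 changes with siRNA 1 and siRNA 2 had a Pearson correlation of 0.379 and a Spearman correlation of 0.279, below the 0.4999 and 0.475 simulated for no effect and a shared control. In H660 they were 0.563 and 0.588 across 13946 genes, against 0.497 and 0.463 simulated; among protein-coding nuclear genes of at least 50 fragments they were 0.713 in H660 and 0.340 in C4-2B MDVR by Pearson, against 0.4998 simulated in each. Correlations of this kind are across genes, which are not independent replicates. The simulated noise came from the difference of siRNA 1 and siRNA 2 and was also given to the lone control. Values below the simulated ones thus do not show that no change was shared. Values above them do not tell a shared effect of the siRNAs from an unusual control. Between the lines the correlation of the mean change was 0.0484 over 11196 genes, and that of the difference of siRNA 1 and siRNA 2 was −0.00810.

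Between the lines 3 of the 7 lineage lists were called. The stem cell (median 0.40, adjusted p = 0.579), luminal (median 0.75 but mean −0.09, 0.813), basal (−0.65, 0.579) and epithelial to mesenchymal transition (−0.85, 0.234) lists were not. Higher in H660, in log2 units with 3 libraries per line, were the protease gene PLAU (8.81), the adhesion gene CEACAM6 (8.27), the antigen-presentation gene CD74 (8.07) and WFDC2 (7.21), and the matrix gene SPON2 was at −8.93 ± 0.29, with 602, 772 and 354 FPKM in the C4-2B MDVR libraries. PAGE1 (−8.20), FOLH1 (−7.60) and SPDEF (−7.22) were lower in H660 as well. Of 44 neuroendocrine genes, 40 were higher in H660 and 2 lower adjusted over the list alone, and 42 passed over all genes, with a median of 2.67 (adjusted p = 3.73e-13, and adjusted p = 0.0782 with an estimated correlation); NKX2-1 (7.18), UCHL1 (6.91) and SOX2 (6.87) were among the highest. Of 38 androgen receptor genes, 30 were lower and 4 higher adjusted over the list alone, and 34 passed over all genes, with a median of −2.39 (adjusted p = 8.82e-08, and adjusted p = 0.819 with an estimated correlation); KLK3 was at −7.17. The neural lineage list had 21 genes higher and 7 lower of 31 (median 1.23, adjusted p = 0.00393, and adjusted p = 0.514 with an estimated correlation), with the axon guidance receptor gene ROBO1 (4.20) and the adhesion gene NRCAM (4.04) among the highest.

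Further lists separated the lines by camera, each with adjusted p = 0.819 with an estimated correlation. Higher in H660 were G1 and S phase (median 0.77; 35 genes higher and 5 lower adjusted over the list alone; CCNE2 2.40, MCM3 2.33), G2 and M phase (0.61; 30 and 5) and NF-kB (1.65; 15 and 3; CXCL8 4.58, IL32 3.63). Lower in H660 were ribosomal proteins (−1.39; 42 of 47 lower; RPL3 −2.81), cholesterol and fatty acid synthesis (−1.12; 28 of 33 lower; FASN −4.34, ACSL3 −4.17), hypoxia (−1.11; 26 of 36; ALDOC −5.61), the stress response (−0.93; 20 of 35), oxidative phosphorylation (−0.69; 27 of 38) and MYC targets (−0.66; 26 of 38). In all, 5946 genes passed the limma test with at least a 2-fold difference, 3143 higher and 2803 lower in H660. The balance moved with the scaling: voom gave 4431 higher and 3064 lower (7495 in all), leaving out mitochondrial genes 3796 and 2358, and quantile normalization 2745 and 3043. The G2 and M phase call was lost without C4-2B MDVR knockdown replicate 1 (adjusted p = 0.0505) or H660 knockdown replicate 1 (0.053), and the stress response call without C4-2B MDVR knockdown replicate 2 (0.0805). Of 12 lists called, 0 held with an estimated correlation, and fry called 19. Leaving out mitochondrial genes moved the median of all genes to 0.19.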

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

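All explanation tests in this part were chosen only after the result they bear on was seen; the split of the libraries was chosen before. The effect of the knockdown differed between the lines in 6 gene lists, by a test of the difference itself, H660 minus C4-2B MDVR in log2 units. The medians were −0.74 for interferon response, −0.83 for p53 targets, −1.17 for mitochondrially encoded transcripts, 0.23 for G2 and M phase, −0.20 for hypoxia and glycolysis (0.04 with short RNAs left out) and 0.10 for cholesterol and fatty acid synthesis. With an estimated correlation the adjusted p of these lists ran from 0.283 to 0.83.

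Interferon and p53 target genes were higher in both C4-2B MDVR knockdown libraries than in their control, with medians of 0.84 and 0.79. Scaling against the control's smaller mitochondrial share is argued against, since with mitochondrial genes left out the medians were 0.83 and 0.72. With short RNAs left out and the libraries rescaled, which moved the median of all genes to −0.18, they were 0.65 and 0.50. Of leukocyte genes CD8A was highest, at 1.24 FPKM against 0.796 in the control. That is above the bound of 1 set for that test, so leukocyte reads were open by it. A second test, on CD74 and PTPRC, which leukocytes express at a high level, was added after their values had been seen. Its outcome was thus known when it was set. These genes reached 0.109 and 0 FPKM, which argues against leukocyte reads as a description, not as a test set in advance. Loss of PLXND1, the difference the design names, cannot be told apart from other effects of the siRNAs. Over the members expressed in the line, siRNA 1, which left less PLXND1, had the interferon median higher by 0.373 than siRNA 2. The p53 median over expressed members was lower with siRNA 1 (−0.356), in 2 libraries. Over all 35 measured interferon members the medians were close, at 0.73 with siRNA 1 and 0.68 with siRNA 2. Over all 27 measured p53 members they were 0.68 and 0.97. The control of C4-2B MDVR is 1 library, so an unusual control cannot be told apart from a response to the siRNAs.

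Mitochondrially encoded transcripts were higher in both C4-2B MDVR knockdown libraries, with a median of 1.31. A scaling factor per library moves all genes alike and is argued against, since the median of all genes was 0.02. With short RNAs left out and the libraries rescaled, which hardly alters that gap, the 13 transcripts exceeded all genes by 1.19 (standard error 0.0623). Standard errors in this paragraph are over genes of the same libraries and do not hold the spread between libraries. They are those of the mean, while the values beside them are medians. Quantile normalization, which fixes the top ranks, gave 0.01 and decides nothing. A difference in the capture of RNA without a long poly(A) tail stays open: all 15 measured replication-dependent histone genes, which lack that tail, had a median of 0.127 (standard error 0.15), and the 11 with a mean FPKM of at least 1 in the line had 0.457 (0.193). The restriction to 11 was made after the first value was seen, because 4 of the 15 were near the floor; by the bound of 0.5 set for it the first value alone would have argued against the explanation. The control had 3.38% of its fragments from mitochondrial genes against 6.83% in the lowest of the other 5 libraries, and with 1 control an unusual control library cannot be told apart from an effect of the siRNAs.

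PLXND1 was close to its control level in both H660 libraries labelled knockdown, at 83.5% and 82.6%. Counting error that hides a decrease as large as in C4-2B MDVR is argued against, since the lower bounds were no less than 77.6% of the control in H660 and the upper bounds no more than 46.4% in C4-2B MDVR. Whether little of the siRNA reached the H660 cells cannot be told apart from other sources of a weak decrease, since the table holds 0 measures of siRNA uptake.

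The line difference of 5946 genes came from the real split of the 6 libraries. Of the 10 splits into 3 and 3, that 1 alone gave as many, with 0 as the highest count of the others. The 10 splits are too few for a share under 0.05.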

How the results depend on the processing

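The voom fit, the fit without mitochondrial genes and the count among protein-coding genes of at least 50 fragments were tests chosen only after the results were seen. Of 191 alternative values of the main results 137 were kept and 54 were not. A count was kept if it stayed within 1.5 times, or at 0 where the main count was 0. Direction, and which genes or lists were counted, did not enter. The line difference with quantile normalization was thus kept, at 2745 genes higher and 3043 lower against 3143 and 2803. Other values were kept if they stayed within the spread between siRNAs or over resampled genes. Of 581 values of called lists 424 were kept, 146 lost the call and 11 reversed. Named genes kept their sign in 1787 of 1787 values. Apart from PLXND1 they were taken for large changes, in the knockdown comparisons with the same sign in the libraries compared, so few could have reversed. With no filter the genes called were mostly near the floor in the knockdown comparisons: 851 in C4-2B MDVR (780 at 0 in both knockdown libraries and 832 under 1 FPKM on average), 876 in H660 (798 and 861) and 1372 for the difference of the effect (1262 and 1352). A pseudocount of 5 gave 1 gene in both lines and 2462 between lines, and a pseudocount of 0.1 gave 1 in H660. A filter of 1 FPKM in both lines gave 2 genes in H660, 1 for the difference of the effect and 3068 between lines; a filter of 5 FPKM gave 3 in C4-2B MDVR, 2 in H660 and 3796 between lines, with fewer genes tested. An adjusted p of 0.10 gave 2 genes in C4-2B MDVR and 1 in H660, and quantile normalization and leaving out short RNAs gave 1 each in H660. With the siRNA number as a replicate block the gene counts were 0 in both lines, 0 in C4-2B MDVR, 1 in H660, 0 for the difference of the effect and 5993 between lines, and the list counts 14, 13, 1, 6 and 12; oxidative phosphorylation in C4-2B MDVR (0.0643) and hypoxia in the difference of the effect (0.0552) lost their call there. Genes at least 2-fold changed with both siRNAs were 464 at 1.5-fold, 273 and 43 with pseudocounts of 0.1 and 5, 62 above 5 FPKM and 46 among coding genes in C4-2B MDVR, and 368, 223, 10, 20 and 15 in H660. The correlation of the siRNAs was 0.408, 0.359 and 0.355 in C4-2B MDVR and 0.508, 0.625 and 0.716 in H660 with pseudocounts of 0.1 and 5 and above 5 FPKM, and that of the difference of siRNAs between lines above 5 FPKM was −0.0423. PLXND1 in H660 was −0.25 with median-ratio scaling and −0.27 with a pseudocount of 0.1. Called lists were 0 in all 5 comparisons with an estimated correlation, and 0, 0, 0, 0 and 19 by fry. Camera with an estimated correlation also missed a simulated shift of the interferon list by 1 log2 unit in C4-2B MDVR (adjusted p = 0.216) and in H660 (0.0958). It missed the shift in the difference of the effect (0.277) but not in both lines (0.0128). The simulated genes were drawn independently, so these misses do not show that calls at the preset correlation hold. With each library left out in turn, 0 genes passed in any knockdown comparison and 5851 to 6028 between lines; called lists ran from 1 to 15 in both lines, 9 to 14 in C4-2B MDVR, 0 to 2 in H660, 3 to 11 for the difference of the effect and 11 to 13 between lines; PLXND1 ran from −1.71 to −1.04 in C4-2B MDVR and −0.25 to −0.23 in H660. Without the control of 1 line the effect in both lines was that of the other line alone, and without a knockdown library the fit per line took its spread from the 1 pair of the other line. Lists reversed, by adjusted p, with quantile normalization for ribosomal proteins in both lines (0.614) and in C4-2B MDVR (0.626). With a library left out, the adjusted p in both lines ran from 3.9e-08 to 0.972 for G2 and M phase, which had the other sign in H660 alone, without the C4-2B MDVR control (0.724), and reversed without C4-2B MDVR knockdown replicate 1 (0.972), from 0.00269 to 0.96 for hypoxia, with the other sign in H660 alone, from 1.21e-07 to 0.957 for MYC targets, reversed without that knockdown replicate 1, and from 3.23e-07 to 0.605 for ribosomal proteins, reversed without C4-2B MDVR knockdown replicate 2. In C4-2B MDVR it ran from 2.12e-13 to 0.982 for G2 and M phase, from 4.02e-11 to 0.32 for MYC targets and from 1.09e-06 to 0.861 for luminal genes, all reversed without knockdown replicate 1, and from 7.04e-11 to 0.0881 for ribosomal proteins, reversed without knockdown replicate 2. Beyond the numbers of genes tested and of libraries, the cause was not tested. The effect in a line without its control, and the difference of the effect without either control, could not be fitted; the alternatives planned in case the file held counts were not run, since it held FPKM, and the fragment numbers recovered from it were fitted by voom alone. In the library of lowest depth, with 17655802 fragments, PLXND1 rested on 490 fragments.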

Other observations

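The test on the sensors of introduced RNA was chosen before its result was seen, and the gene sets of this part and the test of the stress list's arms only after. Of 6 interferon genes, 4 were seen in the C4-2B MDVR knockdown libraries and not in their control: the type I gene IFNB1 and the type III genes IFNL1, IFNL2 and IFNL3. The type I genes IFNA1 and IFNA2 were at 0 in every library. IFNB1 was listed at 0 in the control and at 1.73 and 0.645 FPKM with siRNA 1 and siRNA 2 (30 and 9 fragments), IFNL1 at 0, 5.39 and 1.29 FPKM, IFNL2 at 0, 2.56 and 1.34 FPKM and IFNL3 at 0, 3.93 and 0.878 FPKM. CXCL10, a chemokine gene induced by interferon, was at 0, 2.11 and 5.08 FPKM. Of 7 genes of interferon receptor signalling, 5 were higher in the H660 control than in the C4-2B MDVR control, with a median of 0.74 log2 units for the set, from −1.12 for the receptor gene IFNAR1 to 2.55 for the kinase gene JAK1. The class II antigen-presentation genes CD74 (270, 279 and 311 FPKM) and HLA-DRA (77.5, 72.6 and 87.9 FPKM) were high in all 3 H660 libraries, while PTPRC, a marker of all leukocytes, stayed at or near 0 in both lines.

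The interferon list was not called in H660, and a candidate explanation was that H660 lacks the sensors of introduced RNA. Over 10 sensors and signalling genes the median was 0.507 log2 units higher in the H660 control than in the C4-2B MDVR control, which argues against low transcript levels of the sensors. Whether the siRNAs reached those cells to the same extent was not measured.

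In the stress response list, genes driven by ATF4 may have moved apart from those of the endoplasmic reticulum, as translation stress without endoplasmic reticulum stress would have it. The endoplasmic reticulum arm held chaperones together with the transcription factor gene XBP1 and the degradation genes HERPUD1, SEL1L and EDEM1. ATF4 and DDIT4 were in neither arm. The median of the ATF4 arm exceeded that of the endoplasmic reticulum arm in 4 of the 4 knockdown libraries, but by more than 2 standard errors in the 2 H660 libraries alone. The differences were 0.261 (standard error 0.0669) and 0.39 (0.078) in H660, and 0.00697 (0.159) and 0.375 (0.201) in C4-2B MDVR. These standard errors are over genes within 1 library, so they do not measure the spread between libraries. They are those of a difference of means, while the differences are of medians. In C4-2B MDVR the arms were at 0.08 and 0.07 with siRNA 1 and at 0.92 and 0.54 with siRNA 2. With siRNA 2 all 15 genes of the endoplasmic reticulum arm were above the control, though XBP1 by 0.006 only. In H660 they were at 0.42 and 0.16 with siRNA 1 and at 0.60 and 0.21 with siRNA 2. The endoplasmic reticulum arm's own values with siRNA 2 leave endoplasmic reticulum stress open.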
